A study of Homo sapiens with 9 samples.

How the data were processed

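RNA sequencing libraries from RD cells, an established human embryonal rhabdomyosarcoma line, were compared between a non-targeting hairpin (shNT) and a pair of hairpins against TRPS1 (shTRPS1#1 and shTRPS1#2), with 3 libraries in each of the 3 groups. Per the labels' protocols, cells received doxycycline at 1 µM, spent 2 days in growth medium with 10% fetal bovine serum and then 10 days in differentiation medium with 2% horse serum. Total RNA was extracted with phenol-chloroform, and libraries were made from 180 ng of RNA after poly(A) selection with an NEBNext Ultra II kit, per the labels' protocols. Each sample was placed in its group by its own label. The labels number the libraries 1 to 3 in every group and do not say whether a number marks a shared day or culture, nor whether the libraries came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

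The authors deposited a table of read counts per gene, with 60676 Ensembl gene identifiers and 9 libraries, and a table of RPKM for the same genes and libraries. The submitters' processing notes name bcl2fastq 2.20.0.422, STAR 2.7.2b, featureCounts 1.6.5 and the GRCh38 build, without saying in which step each was used. The annotation release, the strand setting and the treatment of reads with several alignments are not given in the sources used here. The deposited counts were whole numbers with no normalization. The deposited RPKM values equalled the counts divided by gene length and by the library's total, with a largest relative deviation of 3.3e-14, so they carry the same information as the counts. Because the strand setting is not stated, reads of genes that overlap on opposite strands could not be told apart, and pseudogenes can take reads from their parent genes.

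Totals ran from 21965744 to 23289062 counts per library. Of the identifiers, 60357 were matched to a gene symbol through a table of gene names, and the 319 without a name held 0.107% of all counts. A further count of 24533 genes had no read in any library. Coordinates, transcript lengths and 3' UTR sequences came from GENCODE release 29 on GRCh38, which may differ from the annotation the authors counted on.

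Counts were tested with edgeR 4.0.16 (quasi-likelihood test) in R 4.3.3. Genes were kept by the package's expression filter at its default minimum of 10 counts, which left 17014 genes, 13482 of them protein coding. Libraries were scaled with TMM factors, and a model with a mean per group was fitted to all 9 libraries, which therefore share their estimate of the spread (6 residual degrees of freedom per gene). Contrasts were shTRPS1#1 minus shNT, shTRPS1#2 minus shNT and shTRPS1#2 minus shTRPS1#1. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 17014 genes, and a gene was counted for both hairpins when it was called in both contrasts against shNT with the same sign. Levels are given as counts scaled to a common library size (CPM) with TMM factors, as mean ± SD, and fold changes as log2 with a standard error (SE). This SE was computed as the absolute log2 fold change divided by the square root of the test's F value. It is therefore approximate, and for large changes from low counts it may be too small. The 95% intervals of TRPS1 span 1.96 of these SE each way and are approximate too.

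A set of 28 gene lists, with 717 distinct genes, was written before the data were examined. It covered skeletal muscle structure and regulation, the cell cycle, signalling pathways, stress responses, markers of other cell types, and ribosomal and mitochondrial genes as signs of RNA composition. The symbol MYL11 was added afterwards as another name of MYLPF in the sarcomere list. Lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 28 lists in each contrast, and again with camera at a correlation estimated from the data and with fry. Camera compares a list with all other genes tested, and fry tests whether a list's genes move on balance in 1 direction.

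The genes named were chosen by a rule fixed at the same time as the lists. It took TRPS1, the 10 largest rises and 10 largest falls shared by both hairpins (by the smaller of the absolute fold changes), the 4 largest rises and 4 largest falls with each hairpin, and the 5 largest each way between the hairpins. These were restricted to an average log2 CPM of at least 1, a proper gene symbol and libraries that did not overlap between the groups compared. Up to 5 members of each list with the smallest adjusted p in both contrasts, plus 1 member called in the opposite direction, could also be named, as could every measured member of the lists of myogenic regulators and GATA factors. Some genes that met the rule are not reported here.

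Because both hairpins were compared with the same shNT libraries, 20 sets of counts with no difference between groups were simulated with the observed means and dispersions, and the overlap of calls and the correlation of fold changes were computed in each. The edgeR fit was tested on simulated data in which genes changed by known folds among 16813 genes tested. For shTRPS1#2 minus shNT it recovered 42% of 50 genes changed by 0.25 on the log2 scale, 67.3% of 49 genes changed by 0.5, 83.3% of 48 genes changed by 1 and 100% of 49 genes changed by 2, and 8.33% of its calls were false. For shTRPS1#1 minus shNT the recovered shares were 44%, 72%, 78.3% and 100%, and 5.33% of the calls were false. Camera called a simulated set shifted by 0.2 and called 0 of 4 unshifted sets. The simulated genes were drawn independently, so this does not show how often camera falsely calls lists of correlated genes. With shTRPS1#2 the estimated correlation was 0.424 for the mitosis list and 0.643 for the ribosome list.

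The alternatives fixed beforehand were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no filter, a filter of 10 counts in every library of a group, the replicate number as a block, fits of only the groups compared, a minimum 2-fold change, limma on log2(RPKM + 0.5), on log2(RPKM + 0.1) and on log2(RPKM + 1), estimated correlations, fry, and leaving out each library in turn. Leaving out the genes with a 3' UTR heptamer and removing a trend with transcript length and GC content were added after seeing the data.

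For the closing tests, the 3' UTR of each gene's transcript with the longest coding sequence was searched for all heptamers, in 11109 genes with an average log2 CPM of at least 2. Fold changes limited to ±1 were compared between genes with and without each heptamer, with 3' UTR length and GC content projected out (Python 3.11.15, NumPy 2.4.6). With 11109 genes and a simulated shift of -0.1, the scan ranked the shifted heptamer 1 and estimated -0.0808. No sample and no column of the tables was left out.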

Results

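RD cells carry the features of embryonal rhabdomyosarcoma, a soft tissue tumour of childhood whose cells express muscle transcription factors but differentiate incompletely. TRPS1 is a zinc finger transcription factor of the GATA type that acts mainly as a repressor. The series title poses the question of how TRPS1 bears on myogenic differentiation in this tumour, and gene expression was measured by poly(A) RNA sequencing after 10 days in differentiation medium. There were 3 libraries with a non-targeting hairpin (shNT), 3 with shTRPS1#1 and 3 with shTRPS1#2, all under doxycycline. Totals were 22480288 to 22945103 counts in the shNT libraries, 22302248 to 23289062 with shTRPS1#1 and 21965744 to 22378996 with shTRPS1#2. In a principal component analysis of log2 CPM, the first component (24.8% of the variance) separated the hairpins against TRPS1 from each other, and the next (21.8%) separated both from shNT. Every pair of libraries within a group differed by more than sampling noise, with a chi-square per degree of freedom of 1.27 to 2.85.

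The targeted gene was lower in every library of both knockdown groups, by a modest amount. TRPS1 (ENSG00000104447, chromosome 8, 115408496 to 115809673, minus strand, GRCh38) stood at 73.5 ± 3.29 CPM with shNT (SD, n = 3), 57.8 ± 3.43 CPM with shTRPS1#1 and 57.4 ± 1.39 CPM with shTRPS1#2. The raw counts were 1744, 1583 and 1695 with shNT, 1237, 1371 and 1299 with shTRPS1#1, and 1242, 1313 and 1280 with shTRPS1#2. The log2 fold change was -0.35 ± 0.04 (SE) with shTRPS1#1 (edgeR adjusted p = 2.27e-08) and -0.36 ± 0.04 with shTRPS1#2 (edgeR adjusted p = 1.02e-08). TRPS1 mRNA was thus at 78.6% of the shNT level with shTRPS1#1 (95% interval 74.0 to 83.5) and at 78.1% with shTRPS1#2 (95% interval 73.5 to 82.9). The difference between the hairpins was -0.01 ± 0.05 (edgeR adjusted p = 0.913). TRPS1 protein was not analysed here.

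**Figure D1:**
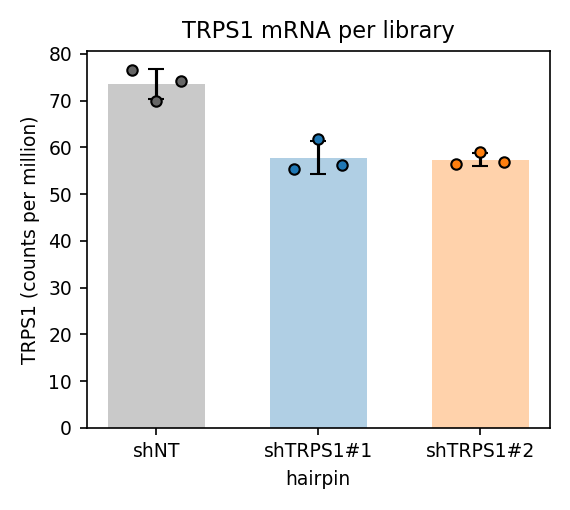
TRPS1 level in CPM (vertical axis) in each hairpin group (horizontal axis); points are libraries, bars the mean of 3 libraries and error bars the SD. All 6 libraries with a TRPS1 hairpin lay between 55.5 and 61.8 CPM, below the 3 shNT libraries at 70.0 to 76.5 CPM.

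With both hairpins, genes of the contractile apparatus of skeletal muscle rose together. Of 42 sarcomere genes tested, 35 rose and 0 fell with shTRPS1#1, with a median log2 fold change of 0.47, and 36 rose and 0 fell with shTRPS1#2, with a median of 0.57. Adjusted over the list alone, 36 and 37 rose. The developmental myosin heavy chains MYH3 (0.72 ± 0.03 and 0.69 ± 0.03 with shTRPS1#1 and shTRPS1#2, SE, 3 libraries per group) and MYH8 (1.34 ± 0.05 and 0.83 ± 0.05), the slow myosin MYH7 (1.13 ± 0.04 and 0.72 ± 0.04), the Z-disc protein MYOZ2 (0.84 ± 0.04 and 0.72 ± 0.04) and the M-band protein MYOM1 (0.73 ± 0.04 and 0.75 ± 0.04) were among them. Camera called the list higher with both hairpins (adjusted p = 2.65e-125 and 9.73e-116). Both calls held with an estimated correlation (adjusted p = 0.000245 and 0.000321), and the list was not called between the hairpins (camera adjusted p = 0.832, median difference 0.03), where 16 of its genes were higher and 8 lower with shTRPS1#2.

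Further parts of the muscle programme rose with the sarcomere. Of 22 genes of excitation-contraction coupling, which link the membrane signal to calcium release, 14 rose and 0 fell with shTRPS1#1 (17 and 0 adjusted over the list alone), and 14 rose and 2 fell with shTRPS1#2 (15 and 2). They included the calcium buffer CASQ2 (1.12 ± 0.04 and 0.69 ± 0.04), the calcium channel subunit CACNA1S (0.64 ± 0.04 and 0.47 ± 0.04) and triadin, TRDN (0.60 ± 0.06 and 0.57 ± 0.06). Of 27 genes of muscle assembly and turnover, 19 rose and 1 fell with shTRPS1#1 and 17 rose and 3 fell with shTRPS1#2 (19 and 1, and 18 and 3, adjusted over the list alone). Here KLHL31 (1.02 ± 0.07 and 0.97 ± 0.07), the myosin chaperone UNC45B (0.33 ± 0.03 and 0.48 ± 0.03) and the muscle methyltransferase SMYD1 (0.27 ± 0.03 and 0.40 ± 0.03) rose, while LMCD1 fell (-0.26 ± 0.04 with both). Camera called both lists higher with shTRPS1#1 (adjusted p = 1.68e-28 and 1.16e-24) and with shTRPS1#2 (7.44e-24 and 4.22e-10), also with an estimated correlation (adjusted p = 0.000742 and 0.000763, then 0.00131 and 0.00691). The list of muscle assembly and turnover was called lower with shTRPS1#2 than with shTRPS1#1 (camera adjusted p = 0.00204, 0.13 with an estimated correlation).

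Genes of fusion, membrane and synapse moved less uniformly. Of 25 genes of myoblast fusion and the muscle membrane, 12 rose and 4 fell with shTRPS1#1 and 12 rose and 5 fell with shTRPS1#2 (13 and 4, and 13 and 5, adjusted over the list alone). The fusion proteins moved apart: MYMK, myomaker, rose (0.49 ± 0.06 and 0.44 ± 0.06) and MYMX, myomixer, fell (-0.67 ± 0.08 and -0.77 ± 0.08). Caveolin 3 (CAV3, 0.84 ± 0.08 and 0.92 ± 0.08), dystrophin (DMD, 0.47 ± 0.04 and 0.33 ± 0.04) and TMEM182 (0.50 ± 0.05 and 0.63 ± 0.05) rose. Camera called this list higher (adjusted p = 0.00109 and 0.000425), but not with an estimated correlation (adjusted p = 0.121 and 0.0698). Of 14 genes of the neuromuscular junction, 5 rose and 1 fell with shTRPS1#1 and 8 rose and 1 fell with shTRPS1#2 (5 and 3, and 8 and 1, adjusted over the list alone), with MUSK (0.23 ± 0.03 and 0.34 ± 0.03) and LRP4 (0.35 ± 0.05 and 0.30 ± 0.05) higher and DOK7 lower (-0.26 ± 0.05 and -0.27 ± 0.05). The list was called higher (camera adjusted p = 0.0245 and 0.00155) but not with an estimated correlation (adjusted p = 0.311 and 0.121), and the shTRPS1#1 call was lost without shNT replicate 2. Of 24 genes of muscle energy metabolism, 3 rose and 1 fell with shTRPS1#1 (4 and 2 adjusted over the list alone) and 8 rose and 2 fell with shTRPS1#2 (9 and 3). Muscle creatine kinase, CKM, rose with both (0.48 ± 0.04 and 0.53 ± 0.04). This list was called with shTRPS1#2 (camera adjusted p = 0.00309, 0.131 with an estimated correlation) and not with shTRPS1#1 (0.0887), and was not called between the hairpins (0.408). With shTRPS1#1 a call was gained with fry (adjusted p = 0.0264), without the count filter and without shTRPS1#1 replicate 2.

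The transcription factors that drive skeletal myogenesis changed in both directions. Of 17 tested, 6 rose and 5 fell with shTRPS1#1 and 4 rose and 5 fell with shTRPS1#2 (6 and 6, and 4 and 5, adjusted over the list alone), and camera did not call the list (adjusted p = 0.301 and 0.938). With shTRPS1#2 the median of the list was 0.04 and its mean -0.007. MEF2C had the largest shared rise of the list (0.46 ± 0.03 and 0.59 ± 0.03). Myogenin, MYOG, rose slightly with both hairpins (0.19 ± 0.04 and 0.20 ± 0.04), whereas MYOD1 rose with shTRPS1#1 (0.20 ± 0.04) and was at 0.04 ± 0.04 with shTRPS1#2 (edgeR adjusted p = 0.557), a difference of -0.16 ± 0.04 between the hairpins (edgeR adjusted p = 0.00554). PAX7, a factor of muscle stem cells, rose with shTRPS1#1 (0.26 ± 0.04) and fell with shTRPS1#2 (-0.31 ± 0.04), and EYA1 did the opposite (-0.21 ± 0.05 and 0.32 ± 0.05). EYA2 fell with shTRPS1#1 (-0.85 ± 0.14) and was at -0.15 ± 0.12 with shTRPS1#2 (edgeR adjusted p = 0.479). PITX3 fell with both (-0.24 ± 0.06 and -0.67 ± 0.06), the shTRPS1#1 call being lost without shTRPS1#1 replicate 2 (edgeR adjusted p = 0.0525). Of 6 GATA family genes tested, 0 rose and 1 fell with each hairpin in edgeR (1 higher and 2 lower, and 0 and 2, adjusted over the list alone). The genes called were GATAD2B with shTRPS1#1 (-0.13 ± 0.04) and GATAD2A with shTRPS1#2 (-0.13 ± 0.04), both cofactors of the NuRD repressor complex. The GATAD2B call was lost in limma on RPKM and without shNT replicate 1 or shTRPS1#1 replicate 3, and that of GATAD2A without shTRPS1#2 replicate 2. Camera did not call the list (adjusted p = 0.619 and 0.42).

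Over all genes, 2285 were called with shTRPS1#1 (1208 higher, 1077 lower) and 3213 with shTRPS1#2 (1533 higher, 1680 lower). Which direction held more genes depended on the scaling, for these contrasts and for the one between the hairpins. The changes were small, with a median absolute log2 fold change of 0.25 and 0.24 among the calls, and 137 and 120 genes were both called and changed at least 2-fold. Both hairpins changed 992 genes in the same direction (589 higher, 403 lower) and 174 in opposite directions. Independent lists of these sizes would share 108.8 higher and 106.3 lower genes, with 216.3 in opposite directions. Simulated groups without any change had 0 calls with either hairpin, so their shared count of 0 does not gauge what shared controls add. Part of the excess may come from the shared shNT libraries, which were not divided between the contrasts. Across 17014 genes, which are not independent replicates, the fold changes of the hairpins correlated with a Pearson r of 0.451 and a Spearman rho of 0.393. Their covariance was 0.0296, against 0.0119 in the simulations, where r averaged 0.497 from the shared controls alone.

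**Figure D2:**
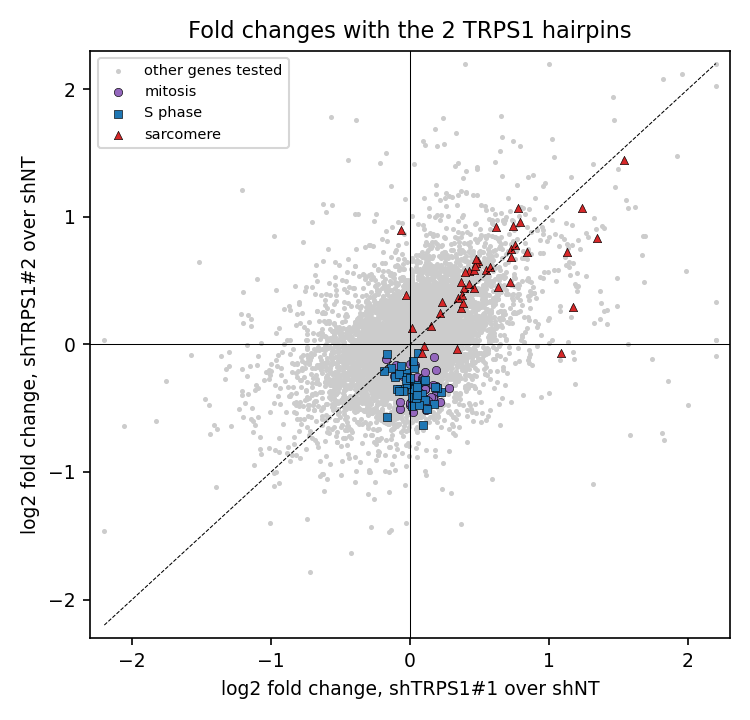
Log2 fold change over shNT with shTRPS1#1 (horizontal axis) and with shTRPS1#2 (vertical axis), 1 point per gene tested (17014); points beyond ±2.2 are drawn at the edge, and the dashed line marks equal change. Sarcomere genes lie to the upper right, with medians of 0.47 and 0.57, and mitosis and S phase genes lie below the horizontal line, with medians of -0.33 and -0.34 with shTRPS1#2.

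The largest rises shared by both hairpins included the muscle genes MYH2 (1.24 ± 0.16 and 1.07 ± 0.17) and KLHL31. IGFBP3, which binds insulin-like growth factors (chromosome 7, 45912245 to 45921874), went from 110.2 ± 1.62 CPM to 276.4 ± 3.73 CPM and 219.1 ± 9.54 CPM (log2 fold changes 1.33 ± 0.04 and 0.99 ± 0.04). The pentraxin PTX3 (1.56 ± 0.16 and 1.13 ± 0.18), the complement component C7 (1.00 ± 0.19 and 2.48 ± 0.15), UNC80 (0.95 ± 0.08 and 1.24 ± 0.07) and WIPF3 (0.95 ± 0.05 and 0.90 ± 0.05) rose as well. RPS4XP2 (1.47 ± 0.22 and 1.76 ± 0.21) is a pseudogene that can share reads with its parent, and GRIP2 (1.12 ± 0.16 and 0.95 ± 0.17) overlaps SLC6A6 on the other strand.

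The largest shared falls included a receptor kinase and a driver of the cell cycle. The receptor tyrosine kinase ALK went from 15.7 ± 1.97 CPM to 7.96 ± 0.95 CPM and 7.25 ± 1.04 CPM (-0.98 ± 0.09 and -1.11 ± 0.10). Cyclin D1, CCND1 (chromosome 11, 69641087 to 69654474), went from 235.4 ± 3.48 CPM to 133.6 ± 3.44 CPM and 129.4 ± 6.41 CPM (-0.82 ± 0.04 and -0.86 ± 0.04); it overlaps the lower expressed LTO1. The laminin chain LAMB3 (-0.97 ± 0.10 and -1.0 ± 0.10), the matrix protein periostin, POSTN (-1.02 ± 0.14 and -0.81 ± 0.14), TNFAIP8L3 (-0.94 ± 0.11 and -1.08 ± 0.11), the Ras-like RASD1 (-0.88 ± 0.07 and -0.85 ± 0.07), the mannosidase MAN1A1 (-0.68 ± 0.14 and -0.75 ± 0.15) and TRG-AS1 (-0.72 ± 0.11 and -0.68 ± 0.11) also fell. H1-9P, a transcribed pseudogene, fell as well (-0.73 ± 0.16 and -0.71 ± 0.16).

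Genes of cell cycle exit, targets of YAP and markers of other muscle types also moved with both hairpins. Of 22 genes of cell cycle exit, 1 rose and 7 fell with shTRPS1#1 and 1 rose and 8 fell with shTRPS1#2 (1 and 8, and 1 and 11, adjusted over the list alone). The gene that rose was the CDK inhibitor CDKN1A (0.60 ± 0.04 and 0.36 ± 0.04), and those that fell included cyclins D1 and D2 (CCND2, -0.32 ± 0.03 and -0.30 ± 0.03), which promote the cycle rather than end it. Camera called this list lower (adjusted p = 0.0041 and 2.9e-05), but not with an estimated correlation (adjusted p = 0.173 and 0.0658), and the shTRPS1#1 call was lost without the genes that carry a 3' UTR heptamer. Of 24 YAP and TEAD targets, 7 rose and 1 fell with shTRPS1#1 and 10 rose and 3 fell with shTRPS1#2 (8 and 2, and 11 and 3, adjusted over the list alone). ANKRD1 (1.27 ± 0.04 and 0.87 ± 0.04), which is also a muscle gene, IGFBP3 and CRIM1 (0.44 ± 0.04 and 0.29 ± 0.04) led them. Camera called the list higher (adjusted p = 2.05e-11 and 1.05e-08), also with an estimated correlation (adjusted p = 0.00196 and 0.00596).

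Some smooth muscle markers rose too, as did cardiac markers that are mostly shared with other lists. Of 12 smooth muscle genes, 6 rose and 1 fell with shTRPS1#1 and 7 rose and 1 fell with shTRPS1#2 (6 and 1, and 8 and 1, adjusted over the list alone). SYNPO2 (0.43 ± 0.03 and 0.59 ± 0.03) and TPM1 (0.22 ± 0.03 and 0.53 ± 0.03), both also used by skeletal muscle, rose, and myosin light chain kinase, MYLK, fell (-0.59 ± 0.05 and -0.29 ± 0.05). Of 9 cardiac genes, 4 rose and 0 fell with shTRPS1#1 and 4 rose and 1 fell with shTRPS1#2 (5 and 0, and 4 and 2, adjusted over the list alone), and 3 of the 4 that rose (ACTC1, TNNT2 and ANKRD1) are also in the sarcomere or YAP lists, without which the list was not tested. Cardiac actin, ACTC1 (0.37 ± 0.03 and 0.28 ± 0.03), and TNNT2 (0.42 ± 0.05 and 0.57 ± 0.05) rose with both hairpins. Camera called smooth muscle (adjusted p = 3.54e-05 and 1.75e-07) and cardiac muscle (3.94e-14 and 5.2e-05) higher, also with an estimated correlation (adjusted p = 0.0158 and 0.00691 for smooth muscle, 0.00429 and 0.0486 for cardiac muscle). The cardiac call with shTRPS1#2 was lost without the count filter.

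With shTRPS1#2, genes of proliferation fell almost as a block, which was not seen with shTRPS1#1. Of 39 mitosis genes, 0 rose and 36 fell with shTRPS1#2 (36 adjusted over the list alone; median -0.33), against 7 that rose and 0 that fell with shTRPS1#1 (8 and 1; median 0.08). Of 40 S phase genes, 0 rose and 37 fell with shTRPS1#2 (38 adjusted over the list alone; median -0.34), against 3 that rose and 2 that fell with shTRPS1#1 (3 and 2; median 0.02). The proliferation marker MKI67 (0.28 ± 0.04 with shTRPS1#1, -0.34 ± 0.04 with shTRPS1#2) and the topoisomerase TOP2A (0.18 ± 0.04 and -0.38 ± 0.04) moved in opposite directions, and UHRF1, which maintains DNA methylation, fell with both (-0.19 ± 0.04 and -0.21 ± 0.04). With shTRPS1#2, camera called mitosis (adjusted p = 1.3e-31) and S phase (3.26e-34) lower, both at an adjusted p of 0.0486 with an estimated correlation. With shTRPS1#1, mitosis was called higher (camera adjusted p = 0.0186, 0.593 with an estimated correlation), a call lost with fry and without shNT replicate 1, shTRPS1#1 replicate 1 or shTRPS1#1 replicate 3, and S phase was not called (0.729). Between the hairpins, 37 of the mitosis genes and 34 of the S phase genes were lower with shTRPS1#2 and 0 were higher (camera adjusted p = 1.11e-45 and 3.73e-36, 0.0895 and 0.0904 with an estimated correlation).

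Ribosomal protein, sterol and stress genes also differed between the hairpins, by smaller amounts. Of 53 cytosolic ribosomal protein genes, 1 rose and 0 fell with shTRPS1#1 (1 and 0 adjusted over the list alone; median 0.04), and 0 rose and 36 fell with shTRPS1#2 (0 and 42; median -0.11), among them RPS16 (-0.18 ± 0.03). Of 25 genes of cholesterol synthesis, 11 rose and 0 fell with shTRPS1#1 (18 and 0; median 0.10) and 0 rose and 9 fell with shTRPS1#2 (0 and 9; median -0.07), as for SCD (0.22 ± 0.03 and -0.14 ± 0.03) and HMGCS1 (0.16 ± 0.03 and -0.14 ± 0.03). Of 25 genes of the unfolded protein response, 5 rose and 2 fell with shTRPS1#1 (6 and 4) and 0 rose and 10 fell with shTRPS1#2 (0 and 13), with the serine synthesis enzyme PHGDH at 0.31 ± 0.04 and -0.32 ± 0.04. Camera called these lists with shTRPS1#2 (adjusted p = 2.5e-11, 0.00155 and 5.51e-05), though not with an estimated correlation (adjusted p = 0.249, 0.184 and 0.106). Between the hairpins, camera called them lower with shTRPS1#2 (adjusted p = 7.62e-20, 9.06e-15 and 1.72e-07), again not with an estimated correlation (adjusted p = 0.335, 0.0895 and 0.13). With shTRPS1#1, cholesterol synthesis (camera adjusted p = 4.28e-06, 0.121 with an estimated correlation) and ribosome (0.0228, 0.69 with an estimated correlation) were called higher, the latter not by fry or without shNT replicate 1 or shTRPS1#1 replicate 3, and the unfolded protein response was not called (0.217).

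Transcripts of the mitochondrial genome, a sign of RNA composition, were lower with both hairpins. Of 13 protein genes, 0 rose and 5 fell with shTRPS1#1 (8 adjusted over the list alone) and 0 rose and 12 fell with shTRPS1#2 (12), as for MT-CO3 (-0.12 ± 0.03 and -0.22 ± 0.03) and MT-CYB (-0.15 ± 0.03 and -0.16 ± 0.03). Mitochondrial genes took 2.71 ± 0.03% of all counts with shNT (SD, n = 3), 2.57 ± 0.03% with shTRPS1#1 and 2.43 ± 0.05% with shTRPS1#2. With shTRPS1#2 this fall ran alongside those in ribosomal, S phase and mitosis genes. With shTRPS1#1 the medians of those lists were 0.04, 0.02 and 0.08, so they did not follow the mitochondrial share there. Camera called the list lower (adjusted p = 0.00213 and 3.17e-10), but not with an estimated correlation (adjusted p = 0.366 and 0.0698).

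Matrix and skeletal genes fell in part. Of 36 extracellular matrix genes, 11 rose and 13 fell with shTRPS1#1 (13 and 15 adjusted over the list alone) and 4 rose and 20 fell with shTRPS1#2 (4 and 24). COL6A1 (-0.29 ± 0.03 and -0.24 ± 0.03) and the proteoglycan BGN (-0.25 ± 0.03 and -0.33 ± 0.04) fell and THBS1 rose (0.39 ± 0.04 and 0.56 ± 0.04), while COL8A1 fell with shTRPS1#1 (-0.64 ± 0.07) and rose with shTRPS1#2 (0.39 ± 0.06). Camera called the list lower with shTRPS1#2 (adjusted p = 2.76e-07, 0.13 with an estimated correlation) and not with shTRPS1#1 (0.265). Of 18 cartilage and bone genes, 1 rose and 5 fell with shTRPS1#1 and 1 rose and 7 fell with shTRPS1#2 (1 and 5, and 1 and 8, adjusted over the list alone), with the cartilage collagen COL2A1 lower (-0.30 ± 0.04 and -0.31 ± 0.04) and STC1 at -0.46 ± 0.04 and 0.41 ± 0.03. This list was called lower (camera adjusted p = 0.0131 and 0.00912), but not with an estimated correlation (adjusted p = 0.0967 and 0.0658).

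Genes of the Notch and Wnt pathways rose and fell, and immediate early genes fell where they were called. Of 24 Notch genes, 5 rose and 1 fell with shTRPS1#1 and 2 rose and 6 fell with shTRPS1#2 (6 and 1, and 2 and 7, adjusted over the list alone). The non-canonical ligand DLK1 rose with both (1.17 ± 0.06 and 0.63 ± 0.06), the target HES1 fell with both (-0.39 ± 0.05 and -0.23 ± 0.05), and NOTCH3 rose with shTRPS1#1 (0.41 ± 0.04) and fell with shTRPS1#2 (-0.16 ± 0.04). The list was called higher with shTRPS1#1 (camera adjusted p = 0.0245, 0.366 with an estimated correlation), a call lost without the count filter and after the removal of a length and GC trend, and was not called with shTRPS1#2 (0.0728), where its median was -0.07 and its mean 0.003. Of 18 Wnt genes, 3 rose and 5 fell with shTRPS1#1 and 4 rose and 3 fell with shTRPS1#2 (5 and 5 with each, adjusted over the list alone), with NKD2 higher (1.23 ± 0.09 and 0.75 ± 0.10) and DKK1 lower (-0.47 ± 0.06 and -0.23 ± 0.06), both antagonists of the pathway, and no call (camera adjusted p = 0.706 and 0.967). Of 22 TGF-beta and BMP targets, 2 rose and 5 fell with shTRPS1#1 and 4 rose and 10 fell with shTRPS1#2 (3 and 6, and 5 and 11, adjusted over the list alone). LTBP2 (-0.24 ± 0.04 and -0.39 ± 0.04), SKIL (-0.28 ± 0.04 and -0.25 ± 0.04) and ID3 (-0.30 ± 0.06 and -0.26 ± 0.06) fell, and the list was not called (camera adjusted p = 0.516 and 0.0728; with shTRPS1#1 its median was -0.01 and its mean 0.07). Of 25 immediate early genes, 0 rose and 7 fell with shTRPS1#1 and 0 rose and 9 fell with shTRPS1#2 (1 and 10, and 0 and 12, adjusted over the list alone), as for DUSP4 (-0.13 ± 0.03 with both), and the list was called lower (camera adjusted p = 0.0129 and 0.00544), though not with an estimated correlation (adjusted p = 0.128 and 0.0901).

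Markers of other lineages and of the interferon response held members that rose and members that fell. Of 18 neural genes, 3 rose and 2 fell with shTRPS1#1 and 5 rose and 1 fell with shTRPS1#2 (3 and 3, and 7 and 2, adjusted over the list alone), with DCX at 1.67 ± 0.08 and 0.70 ± 0.09. Camera called the list with shTRPS1#2 (adjusted p = 0.00314, 0.0486 with an estimated correlation) and not with shTRPS1#1 (0.0774). Of 7 adipocyte genes, 1 rose and 1 fell with shTRPS1#1 and 1 rose and 2 fell with shTRPS1#2 (the same adjusted over the list alone), the fatty acid transporter CD36 rising with both (0.85 ± 0.04 and 0.75 ± 0.04). The shTRPS1#1 call (camera adjusted p = 0.0243, 0.121 with an estimated correlation) came with a mean of 0.08 and a median of -0.02 and was lost without shNT replicate 3, without the count filter (adjusted p = 0.904) and after a trend with transcript length and GC content was removed, and there was none with shTRPS1#2 (0.113). Of 5 epithelial genes, 1 rose and 2 fell with shTRPS1#1 and 0 changed with shTRPS1#2 in edgeR (1 and 2, and 0 and 0, adjusted over the list alone), without a list call (camera adjusted p = 0.408 and 0.967). Of 28 interferon response genes, which double-stranded RNA can induce, 5 rose and 1 fell with shTRPS1#1 and 7 rose and 4 fell with shTRPS1#2 (6 and 1, and 9 and 4, adjusted over the list alone), with IFI6 at 0.29 ± 0.06 and 0.19 ± 0.06. The shTRPS1#1 call (camera adjusted p = 0.0276, 0.498 with an estimated correlation) was lost with fry and without shNT replicate 1, shNT replicate 2 or shTRPS1#1 replicate 3. The list was not called with shTRPS1#2 (camera adjusted p = 0.0679). A call with shTRPS1#2 was gained without the count filter, after removal of the length and GC trend, and without shNT replicate 3 or shTRPS1#2 replicate 2.

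**Figure D3:**
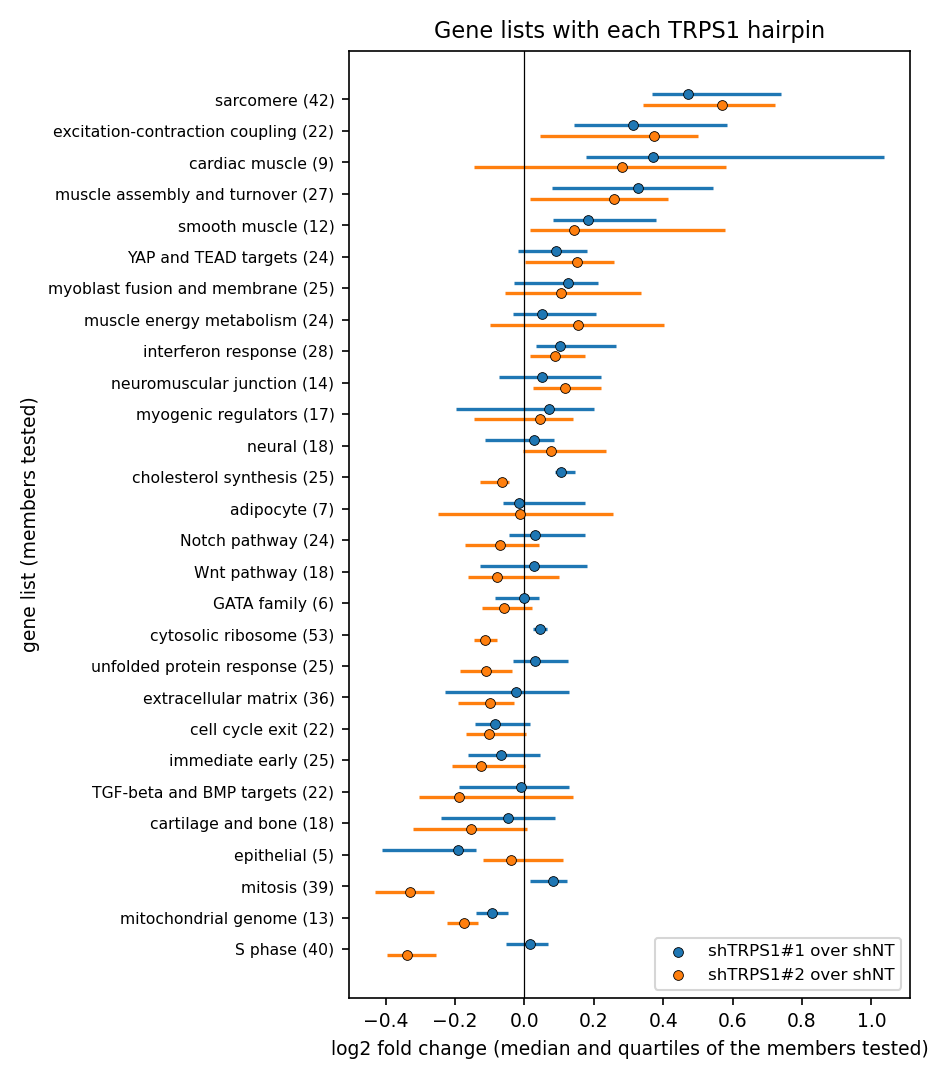
Median log2 fold change over shNT (points, horizontal axis) and quartiles (lines) of the tested members of each of the 28 gene lists (vertical axis, number of members in brackets) with shTRPS1#1 and shTRPS1#2. Sarcomere genes are highest with both hairpins (0.47 and 0.57), and S phase genes are at 0.02 and -0.34.

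Several genes changed far more with 1 hairpin than with the other. With shTRPS1#1, the vesicular glutamate transporter SLC17A8 went from 0.50 ± 0.09 CPM to 10.4 ± 0.80 CPM (4.37 ± 0.17) and was at 0.51 ± 0.17 CPM with shTRPS1#2, and the matrix glycoprotein EMILIN1 (chromosome 2, 27078567 to 27086408) went from 14.6 ± 0.52 CPM to 89.4 ± 5.96 CPM (2.62 ± 0.06) against 18.3 ± 1.04 CPM with shTRPS1#2 (0.33 ± 0.07). ZNF536 (2.00 ± 0.13; -0.48 ± 0.19 with shTRPS1#2, edgeR adjusted p = 0.075) and the growth factor pleiotrophin, PTN (1.68 ± 0.06; 0.48 with shTRPS1#2), rose. THSD4 (-1.48 ± 0.09), the opioid receptor OPRD1 (-1.44 ± 0.10), RUBCNL (-1.39 ± 0.10) and PLA2G4D (-1.33 ± 0.15) fell, and the first 3 also fell with shTRPS1#2 (-0.43, -0.47 and -0.67). With shTRPS1#2, the gap junction gene GJA5 (1.68 ± 0.13) and thyroglobulin, TG (1.75 ± 0.11), rose, and the kinase PTK6 (-1.0 ± 0.14) and CABP7 (-1.03 ± 0.16, overlapping ZMAT5) fell. CABP7 also fell with shTRPS1#1 (-0.65) and did not differ between the hairpins (edgeR adjusted p = 0.139).

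Between the hairpins, 3330 genes differed (1514 higher and 1816 lower with shTRPS1#2), of which 145 differed at least 2-fold. The retinal reductase DHRS3 fell with shTRPS1#1 and rose with shTRPS1#2, a difference of 2.42 ± 0.12. TG (2.14 ± 0.12), SLA, which lies within the TG locus on the other strand (1.67 ± 0.18), GJA5 (1.5 ± 0.12) and C7 (1.48 ± 0.13) were higher with shTRPS1#2. SLC17A8 (-4.33 ± 0.17), ZNF536 (-2.48 ± 0.14), LGI2 (-2.30 ± 0.14), EMILIN1 (-2.29 ± 0.05) and C1QTNF3 (-1.56 ± 0.12) were lower. Of the 992 genes changed the same way by both hairpins, 198 of the higher and 99 of the lower ones also differed in size between the hairpins. Camera called 18 of the 28 lists with shTRPS1#1 (14 higher, 4 lower), 20 with shTRPS1#2 (10 higher, 10 lower) and 10 between the hairpins (all lower with shTRPS1#2). With an estimated correlation, 6, 9 and 0 of these calls held.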

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

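The tests on cell cycle genes, on base composition, on the copies and neighbouring bases of the heptamer and on neighbouring and overlapping genes were chosen only after the result was seen. The lists and the count of genes given first were picked because the test of shTRPS1#2 against shTRPS1#1 itself found a difference. Of the 17014 genes, 3330 differed. Camera called 10 lists, each lower with shTRPS1#2 by its test, and none of these calls held with an estimated correlation. The median log2 differences were -0.43 for mitosis, -0.36 for S phase, -0.17 for cholesterol synthesis, -0.16 for the cytosolic ribosome and -0.12 for the unfolded protein response. They were -0.40 for cardiac muscle, -0.10 for the mitochondrial genome, -0.0671 for the extracellular matrix, -0.0618 for the Notch pathway and -0.0348 for muscle assembly and turnover.

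The fall of mitosis and S phase genes with shTRPS1#2 was not explained by a deeper loss of the target, since TRPS1 differed by -0.0104 between the hairpins (95% interval -0.10 to 0.08). The 3' UTR heptamer described next did not account for the fall as a whole. Of the 79 members, 5 carried the heptamer, with a median difference of -0.63, and the 74 others had a median of -0.38 (quartiles -0.46 and -0.27). A trend with transcript length and GC content left a median of -0.395 (quartiles -0.49 and -0.26). Pairing of shTRPS1#2 with these genes at other sequences, an indirect effect of its other targets, a difference in TRPS1 protein, or a difference between the cultures may lie behind it, and none of these was tested.

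Genes whose 3' UTR holds the heptamer GTACTCA were lower with shTRPS1#2 than other genes: in 666 of 11109 genes the shift was -0.07 on the log2 scale (t = -10.1, rank 1 of 15552 heptamers), against -0.008 (t = -1.16, rank 1851) with shTRPS1#1. In the direct comparison of shTRPS1#2 with shTRPS1#1 the shift of these genes was -0.0586 (t = -8.34, rank 1). With 3' UTR length and all dinucleotide frequencies projected out, the shift with shTRPS1#2 over shNT was -0.0684 (95% interval -0.082 to -0.055), which argues against base composition. In 0 of 200 shufflings of fold changes over genes did any heptamer reach as large a t (highest 5.45), which argues against a chance association. GTACTCA was not the only heptamer beyond the shufflings: AGTACTC (t = -6.45, 576 genes) and TTTTGTA (t = -5.72, 4018 genes) were as well. AGTACTC is not independent of GTACTCA, since it is the same sequence moved by 1 base. Where A stands before GTACTCA, as in 217 genes, both heptamers occur at the same site. The shift of AGTACTC apart from such sites was not tested. The step from 1 copy (614 genes) to at least 2 copies (52 genes) did not separate the hairpins: it was -0.0483 with shTRPS1#2 (95% interval -0.095 to -0.003) and -0.0383 with shTRPS1#1 (-0.106 to 0.015), a difference of -0.0101 (-0.068 to 0.050). Seed pairing by shTRPS1#2 may account for the shift but stays open, since the copies did not decide it and the hairpin sequences are not given in the sources used here; the TRPS1 transcript holds 2 copies of the heptamer, 0 of them in its 3' UTR, and 40.7% of all these heptamers occur in it. For the neighbouring bases, fold changes with shTRPS1#2 over shNT were limited to ±1, with 3' UTR length and GC content projected out, as for the copies. Without a test of the differences, the means with A, C, G and T after the heptamer were -0.105, -0.056, -0.033 and -0.064 (SE 0.013, 0.016, 0.010 and 0.013). Before it they were -0.087, -0.028, -0.039 and -0.058 (SE 0.010, 0.027, 0.013 and 0.011).

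Of the 145 genes at least 2-fold apart between the hairpins, 4 overlapped another of them (SLA lies within TG, and an unnamed gene within ZNF536). That is 2.76% against a 95th percentile of 1.38% in 2000 random sets of like expression. Overlap was counted here between whole gene spans. For TG and SLA no overlap of exons was found in the annotation used here, which argues against shared reads for that pair. For ZNF536 and the unnamed gene within it, shared reads may account for a part of the difference. A neighbour of TG that overlaps no annotated gene also differed, by 1.64, against 2.14 for TG and 1.67 for SLA. Of all 145, 15.9% had another of them within 500 kb that did not overlap it, against a median of 10.3% and a 95th percentile of 16.6% in the random sets. Of the 12 such pairs, 9 differed in the same direction and 3 in opposite directions, against a 95th percentile of 9 over 2000 shufflings of the directions. These values do not decide on a change at a chromosomal site, which stays open. Low counts stay open for many of the genes, as their median average log2 CPM was -0.116.

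Other splits of the libraries were compared with the real ones. The 10 splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 2285 genes with shTRPS1#1, 3213 with shTRPS1#2 and 3330 between the hairpins, and the highest other split gave 0 genes in each; in each of these comparisons 1 of 10 splits reached the real value. For lists, the real splits gave 18 with shTRPS1#1 and 20 with shTRPS1#2, and the highest others gave 11 and 15. For genes changed the same way by both hairpins, only the real one (1) of 100 regroupings of the 9 libraries reached 992. That argues against 9 libraries without group differences. This rests on the spread between libraries and does not exclude that the shNT cultures shared by both comparisons differed by chance. The highest other, 749, was among the 7 that kept a whole real group as control. The remaining regroupings gave 0, so the size of the shared count can be compared with those 7 only. They are too few for a share under 0.05.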

How the results depend on the processing

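The leaving out of genes with the heptamer and the removal of a length and GC trend were chosen after seeing the data. Total counts of genes stayed within 1.5 times the reported ones under each other tool, scaling, filter and pseudocount and under each library left out, but not with a minimum 2-fold change, by construction: 137 with shTRPS1#1, 120 with shTRPS1#2, 20 with both and 145 between the hairpins. DESeq2 gave 1636, 2301, 706 and 2338, and kept 71.0% and 71.2% of the shTRPS1#1 and shTRPS1#2 calls; its count of genes lower with both hairpins was 267. Whether more genes rose or fell depended on the setting: upper-quartile factors gave 1122 higher and 1185 lower with shTRPS1#1, 1626 and 1572 with shTRPS1#2, and 1782 and 1597 between the hairpins. The balance also turned with limma on log2(RPKM + 0.5) with shTRPS1#1 (826 and 857) and between the hairpins (1273 and 1261), and similarly with the other pseudocounts. With shTRPS1#2 it turned with RLE factors (1598 and 1596), with only the groups compared (1566 and 1551) and without shTRPS1#2 replicate 3 (1471 and 1438). With a library left out, the counts ran from 1789 to 2478, from 2498 to 3336, from 770 to 965 and from 2458 to 3519. Without the genes that carry the heptamer, 932 were shared. Estimated correlations, which widen the test for correlated genes, left 6 lists with shTRPS1#1 and 9 with shTRPS1#2; the other settings gave 15 to 19 and 20 to 22. Removing the length and GC trend gave 16 and 21. Libraries with the same replicate number were at most weakly related over all genes (r of deviations from -0.016 to 0.048 over 9 pairs, 0 above 0.1). Principal component 3 (10.2% of the variance) nevertheless placed replicate 1 lowest in each group (-10.1, -8.31 and -13.9). With the replicate block the counts rose to 2505, 3434, 1095 and 3583, with 18 and 20 lists. An effect shared by the replicate 1 libraries was thus not excluded. TRPS1 fell under each setting, by -0.31 to -0.35 and -0.30 to -0.36 outside the leave-one-out fits. The correlation of fold changes ran from 0.415 to 0.519. Of 302 calls among 370 values of named genes, 55 were lost under at least 1 of 20 settings, and 24 values without a call gained one. The calls of SIX4 and IFI6 with shTRPS1#2, of SLA with shTRPS1#1 and of mitochondrial genes with shTRPS1#1 were among those lost, the cause of which was not tested. At this depth the self-test recovered 42% to 44% of simulated changes of 0.25, so many changes of that size may be missed. The self-test changed far fewer genes than were called here, which makes its adjusted threshold stricter. The share missed in the real contrasts is therefore not known.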

Other observations

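The windows along the chromosomes were chosen as a test after the result was seen. DHRS3, a retinal reductase, fell with shTRPS1#1 and rose with shTRPS1#2, from 4.8 ± 0.14 CPM with shNT to 2.08 ± 0.38 CPM and 11.1 ± 0.43 CPM (SD, n = 3).

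Along the chromosomes, 505 windows of 40 expressed genes had median differences between the hairpins from -0.098 to 0.099, so no stretch of this length showed a larger shift. The shift that a gained or lost copy would give in these cells was not determined. A change over a stretch much shorter than 40 expressed genes would not move such a median, so short changes stay open.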
